A study of Mus musculus with 11 samples.

How the data were processed

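RNA from MLL-AF9-transformed mouse granulocyte-macrophage progenitors was measured on 11 1-colour (Cy3) Agilent expression arrays, with 4 arrays before 4-hydroxytamoxifen (0 h), 4 arrays at 48 h and 3 arrays at 96 h. Each sample had 1 scanner file, and a series-wide value table gave 1 column per sample. Per the file headers, the scanner files were written by Agilent Feature Extraction 11.0.1.1, the array design was built on mm9, and nothing was pooled. Per the labels' protocols, RNA was purified with RNeasy columns and labelled with a low-input 1-colour kit.

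The deposited spot intensity used for the main values is the processed signal, which per the file headers is background-subtracted and detrended within each array and not normalized between arrays. The deposited median pixel intensity of each spot and of its local background is not normalized at all. Per the file headers, other deposited columns are 0 or 1 flags per spot for a signal well above background, a non-uniform or population outlier, and saturation. The authors' deposited series table holds log2 values with limma named in the submitters' processing notes, its version not given in the sources used here. Each of its columns matched a normexp correction with an offset of 50 followed by quantile normalization of the scanner values at a correlation of at least 0.99997, with no centring of genes. The columns' medians lay between 6.17 and 6.19.

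Each array held 62976 spots, of which 59305 were not controls. Control spots and spots with an outlier flag (125 to 194 per array) were left out, and no non-control spot was saturated. The main value of a spot was log2 of the processed signal minus the array's 75th percentile over non-control spots, called the scaled log2 signal. Spots of 1 probe were averaged, which gave 55681 probes. Probe accessions were matched without versions to a RefSeq gene table of assembly GRCm38.p6. This gave 27656 probes 1 symbol, gave 0 probes several symbols, and left 28025 probes without a symbol, with 20972 symbols in all. Unmatched probes kept the name in the file, and no coordinates are given because the builds differ.

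Probes well above background on at least 3 of the 11 arrays were kept (34269 probes). The probe with the highest mean over all arrays stood for each gene, which left 25079 genes or unnamed features (14996 with a symbol and 10083 without). For 3731 genes with several kept probes, probes passed the test in opposite directions for 22 genes at 48 h against 0 h, 4 at 96 h against 0 h and 12 at 96 h against 48 h. Where a gene was not well above background on any array of 1 group, a fold is given as "at least", from the bright group's mean against, per array of the dim group, the higher of the lowest signal well above background and the probe's own signal. With members at such bounds, no list median moved by more than 0.24.

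Genes were tested with limma 3.58.1 (lmFit and eBayes, 2-sided moderated test) in R 4.3.3 with the data.table package (1.17.8). The fit held all 11 arrays in 3 groups, with 8 residual degrees of freedom, and Benjamini-Hochberg adjustment ran over all 25079 genes of a comparison. A gene was called at an adjusted p under 0.05. Probes of the floxed genes were also tested each on its own, with adjustment over all 34269 probes. Figures were drawn in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9. Errors are the SE of limma's log2 difference or the SD over arrays.

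Gene lists were compared with all other genes by limma's camera with a preset inter-gene correlation of 0.01, adjusted over all 28 lists and the 3 comparisons. The further lists drawn up later were adjusted apart from these, over the further lists and the 3 comparisons alone. Camera with an estimated correlation and fry, which asks whether a list's genes move on balance 1 way, were alternatives. Among the 28 lists, no call held with an estimated correlation (smallest adjusted p = 0.386). In contrast, fry called 9, 5 and 2 lists at 48 h against 0 h, 96 h against 0 h and 96 h against 48 h. The 28 lists, with 717 entries of which 708 had a probe, covered IL-3 receptor and JAK-STAT5 signalling, the MLL-AF9 and Hoxa leukaemia programme, BCL2 family and caspases, p53 targets, G1/S and DNA replication, G2/M and mitosis, and MYC targets and ribosome biogenesis. Others covered interferon-stimulated genes, germline genes, enzymes and readers of histone H3 lysine 9 and 36 methylation, hypoxia and glycolysis, the unfolded protein and integrated stress response, cholesterol biosynthesis, fatty acid synthesis and LXR targets, lysosome and autophagy, immediate early and AP-1 genes, NF-kB and cytokine genes, and oxidative phosphorylation. Cell type lists covered stem and progenitor cells, granulocyte-monocyte progenitors, mature neutrophils, monocytes and macrophages, dendritic cells, erythroid cells, megakaryocytes, mast cells and basophils, lymphoid cells, and stromal cells.

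The groups, the gene and list tests, the 28 lists, the thresholds, the named-gene rule and all alternatives but 1 were fixed before the data were examined. Some tests of explanations and some further lists came later, as stated where they are reported. The rule named the floxed genes, Il3ra (from background knowledge of the study), the 10 largest rises and 10 largest falls among called genes with a usual symbol for each comparison with 0 h (5 and 5 for 96 h against 48 h), provided that 1 of the groups was well above background on every array, and up to 4 members of each list with the smallest p. Some genes that the rule picked are not reported here. Alternatives were normexp correction with quantile normalization, quantile normalization, the median in place of the 75th percentile, the deposited series table, stricter and no filters on dim probes, the mean over a gene's probes, each probe on its own, only the 2 groups compared, replicate blocks, the array's row on its slide, array weights, trend and robust eBayes, stricter thresholds, split controls and each array left out in turn. The normexp alternative used median pixel intensity in place of the mean, which was not used here. A 75th percentile over the probes well above background on all 11 arrays was added after the data had been seen.

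Replicate numbers come from the sample titles and file names, which differ for the 96 h arrays (1, 2 and 3 in titles, 1, 3 and 4 in file names). Deviations from group means of same-numbered 0 h and 48 h arrays correlated at 0.137 to 0.282 across genes. With the 96 h arrays the correlation was 0.115 to 0.356 by file-name number and -0.042 to 0.356 by title number. By file-name number, 10 of the 11 arrays lay closest to their own number in every other group. File-name numbers were therefore taken to pair the samples, and "same-numbered pairs" refers to them, while a replicate is named by its title number. On all 11 arrays the file-name number was also the array's column on its slide. These correlations therefore cannot tell a shared culture from a shared column, and the block by file-name number is also a block by column. The labels say that there were 4 cell lines and do not tie a number to a line, so p-values measure the spread between these cultures.

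Slide 1 held all 0 h and 48 h arrays and slide 2 held all 96 h arrays, so slide and the 96 h group cannot be told apart. The net signal of negative controls was 12.2 to 13.1 on slide 1 and 15.0 to 15.6 on slide 2. The number of arrays limits the precision. Data were simulated with limma's moderated spread of each gene and 100 genes changed by each fold. In them the gene test recovered 63 of 100 genes changed 2-fold and 90 of 100 changed 4-fold at 48 h against 0 h. It recovered 61 and 89 at 96 h against 0 h, and 61 and 85 at 96 h against 48 h. Among 25071 simulated genes it called 6, 9 and 7 unchanged genes, respectively, and the list test called a list of 26 genes shifted by 0.5 in each comparison and 0 of the other lists. The genes were simulated independently of each other, so these list results do not show how the list test handles correlated genes. Far more genes were called in the real comparisons than were changed here, which eases the adjusted threshold there, so recovery may differ.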

Results

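Transcript levels were measured in L-GMP cells, mouse granulocyte-macrophage progenitors transformed by the MLL-AF9 fusion oncogene. The 4 cell lines came from leukaemic C57BL/6 mice and grew in 20% fetal bovine serum with 10 ng/ml IL-3. They carried floxed alleles of Kdm4a, Kdm4b and Kdm4c (also named Jmjd2a, Jmjd2b and Jmjd2c), which encode histone H3 lysine demethylases, and a tamoxifen-inducible Cre recombinase at the Rosa26 locus. RNA was taken before (0 h, 4 arrays) and 48 h (4 arrays) and 96 h (3 arrays) after addition of 500 nM 4-hydroxytamoxifen, the compound that activates the recombinase. The number of arrays, 3 or 4 per group, limits the precision. Cells given 4-hydroxytamoxifen without floxed alleles were not analysed here, and untreated cells were measured only at 0 h. Loss of the 3 genes, exposure to the drug or the recombinase, and time in culture therefore went together.

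The floxed genes were examined first. The Kdm4c probe (A_55_P2053206) fell from a scaled log2 signal of 0.93 ± 0.23 (SD, n = 4) at 0 h to -4.02 ± 0.32 (n = 4) at 48 h and -3.66 ± 0.15 (n = 3) at 96 h. Its level was 3.24% of that at 0 h by 48 h (log2 difference -4.95, SE 0.17, adjusted p = 8.37e-07) and 4.13% by 96 h (-4.60, SE 0.19, adjusted p = 3.78e-06). The probe was well above background on only 2 of 4 arrays at 48 h, so its remaining level there is uncertain. The Kdm4b probe (A_55_P2028064) fell from 1.53 ± 0.07 to -1.77 ± 0.13 and -1.72 ± 0.17, to 10.2% (adjusted p = 7.28e-07) and 10.5% (adjusted p = 1.86e-06) of its 0 h level. The brighter Kdm4a probe (A_52_P281209) fell from 3.75 ± 0.20 to 2.16 ± 0.18 and 2.55 ± 0.12, leaving 33.1% (adjusted p = 0.00101) and 43.6% (adjusted p = 0.00443). The remaining shares of Kdm4b and Kdm4c depended on background handling: at 48 h the log2 difference of Kdm4b, -3.30, was -2.30 with normexp correction and -2.34 in the deposited table, and that of Kdm4c -2.58 and -2.63. For each of these 3 probes, every array after treatment lay below every 0 h array.

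A dim Kdm4a probe (A_55_P1982585), well above background on 4 of 4, 3 of 4 and 2 of 3 arrays of the groups, gave -3.28 ± 0.34, -3.51 ± 0.30 and -4.74 ± 0.64. It was not called at 48 h (log2 difference -0.23, adjusted p = 0.593) and was called lower at 96 h (-1.46, SE 0.30, adjusted p = 0.0223). Its fall between 48 h and 96 h (-1.23, adjusted p = 0.0313) had no counterpart in the brighter Kdm4a probe (0.40, adjusted p = 0.105). The call against 0 h was lost without any of 0 h replicates 3 and 4 and 96 h replicates 2 and 3 (adjusted p 0.0523 to 0.0606), and the difference was -0.25 with normexp correction and -0.26 in the deposited table. The call between 48 h and 96 h was lost without any of 48 h replicates 1, 3 and 4 and 96 h replicates 2 and 3 (0.0643 to 0.0774), with normexp correction (0.249) and in the deposited table (0.25). The labels do not give the deleted parts of the genes, so a probe outside them would not report deletion. A Kdm4d probe was not well above background on any array and was not tested.

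**Figure D1:**
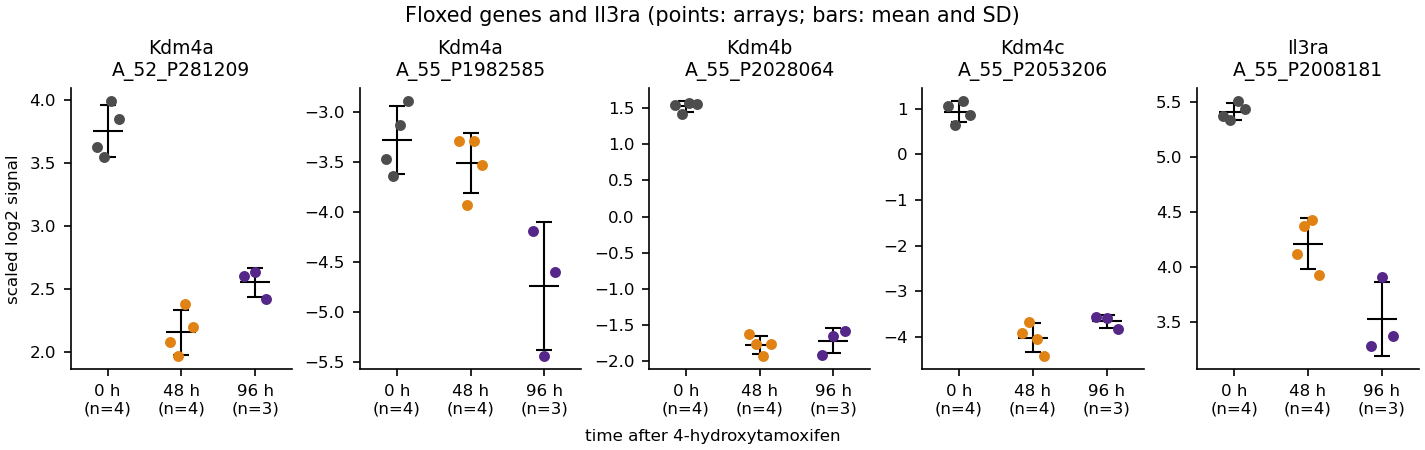
Scaled log2 signal (log2 of the processed signal minus the array's 75th percentile) of each array at 0 h, 48 h and 96 h for the Kdm4a, Kdm4b, Kdm4c and Il3ra probes, with points for arrays and bars for the mean and SD. Kdm4c lay at 0.93 on average at 0 h and at -4.02 at 48 h, and Il3ra at 5.41, 4.21 and 3.52 at 0 h, 48 h and 96 h.

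Il3ra, the alpha chain of the IL-3 receptor, was picked before the data were examined, from background knowledge of the study and not from its labels. It fell from 5.41 ± 0.08 at 0 h to 4.21 ± 0.23 at 48 h and 3.52 ± 0.34 at 96 h, to 43.6% (log2 difference -1.20, SE 0.16, adjusted p = 0.00243) and 27.1% (-1.89, SE 0.17, adjusted p = 0.00137) of the 0 h level. All 4 arrays at 48 h and all 3 at 96 h lay below all 0 h arrays. The further fall from 48 h to 96 h (-0.69, SE 0.17, adjusted p = 0.0305) lost its call without any of 48 h replicates 1, 2 and 3 and 96 h replicates 1 and 3 (adjusted p 0.0568 to 0.115). It was also lost under median scaling (0.0931), without a filter on dim probes (0.0662), with only the 2 groups compared (0.0762) and with the block by title number (0.0504).

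The series aimed to identify target genes of Kdm4a, Kdm4b and Kdm4c, and the comparison of 48 h with 0 h gives the earlier changes. At 48 h, Mpo, the myeloperoxidase of primary granules, rose 20.2-fold (log2 difference 4.33, SE 0.52, adjusted p = 0.00199). Mgarp, a mitochondrial transport regulator induced by hypoxia, rose by 4.18 (SE 0.74, adjusted p = 0.00671) and Fxyd4, a sodium pump regulator, by 3.63 (SE 0.39, adjusted p = 0.00159). Camp, the cathelicidin of secondary granules, rose 5.65-fold (SE of the log2 difference 0.56, adjusted p = 0.0159). The X-linked homeobox gene Rhox5, not well above background on any 0 h array, was at least 2.47-fold higher (adjusted p = 0.00667). Other large rises were those of Glod5 (2.55, adjusted p = 7.4e-04), Smtnl2 (2.37), the tight-junction gene Cgn (2.53) and Ttll9 (2.23). At 0 h, Mgarp and Ttll9 were well above background on 2 of 4 arrays and Cgn on 1.

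Among the largest falls at 48 h besides Kdm4c were Mamdc2 (-5.39, SE 0.84, adjusted p = 0.00426), the potassium channel gene Kcnma1 (-4.10, SE 0.59, adjusted p = 0.00317), Csprs (-4.13, SE 0.47, adjusted p = 0.00179) and the basement membrane collagen gene Col4a1 (-4.21, SE 0.80, adjusted p = 0.00869). Ddit3, the stress-induced transcription factor CHOP, was 14.2-fold lower (-3.82, SE 0.47, adjusted p = 0.00199), and Snhg12, a host gene of small nucleolar RNAs, 13.7-fold lower (-3.78, SE 0.56, adjusted p = 0.00335). Tgfb2 was at least 11.7-fold lower (adjusted p = 0.00179) and the olfactory receptor gene Olfr1362 at least 6.22-fold lower (adjusted p = 0.00229), as neither was well above background on any 48 h array. Kcnma1 was so on 1 of 4. Thbs1, thrombospondin, fell by 4.30 (SE 1.15, adjusted p = 0.029). For each gene named here, all 4 arrays at 48 h lay on the same side of all 0 h arrays. The call of Thbs1 was lost without any of 0 h replicates 1, 3 and 4 and 48 h replicates 3 and 4 (adjusted p 0.0577 to 0.0765) and without a filter on dim probes (0.0558), and that of Smtnl2 under quantile normalization (0.0601). That of Cgn was lost without 0 h replicates 1 or 4 or 48 h replicates 2 or 4 (0.0515 to 0.0554), and that of Ttll9 without 0 h replicates 3 or 4 or 48 h replicates 1 or 2 (0.0574 to 0.0632).

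In all, 4657 of 25079 genes passed the test at 48 h against 0 h, 2644 higher and 2013 lower, and 904 of them changed at least 2-fold. Without a filter on dim probes the count was 2652. The median log2 difference of all genes was 0.12 with the main scaling and -0.10 with the median of each array as the reference, so the split into higher and lower depended on the scaling. It was 1849 higher and 2202 lower with quantile normalization, 424 and 1931 with median scaling, 2278 and 2617 with normexp correction, 2197 and 2691 in the deposited series table, and 3578 and 1753 with the percentile over probes well above background on all arrays. Left-out arrays moved the count to 2947, 2780 and 2769 (0 h replicates 1, 3 and 4) and to 2785 and 2447 (48 h replicates 1 and 4).

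Genes of cholesterol biosynthesis rose together at 48 h. Of 26 measured members, 18 rose and 0 fell (20 and 0 when adjusted over the list alone), among them Hmgcs1 (0.90, adjusted p = 0.00205) and Hsd17b7 (0.96, adjusted p = 0.00775), enzymes of the pathway, and Acat2 (1.34, adjusted p = 0.00847). The list's median log2 difference was 0.74, or 0.62 above that of all genes, and lay above 0 in 4 of 4 same-numbered pairs (camera adjusted p = 5.28e-06, against adjusted p = 0.845 with an estimated correlation). Of 32 hypoxia and glycolysis genes, 18 rose and 4 fell (19 and 6 over the list alone). Risers included Bnip3, a mitophagy receptor (1.34, adjusted p = 0.00122), Egln3, an oxygen-sensing prolyl hydroxylase (1.36, adjusted p = 0.00126), Ankrd37 (2.09, adjusted p = 0.00145) and the glycolytic enzyme gene Pgk1 (0.95, adjusted p = 0.00198). The median was 0.50, or 0.38 above all genes, and lay between 0.40 and 0.58 in the 4 pairs (camera adjusted p = 5.91e-04, adjusted p = 0.509 with an estimated correlation).

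The unfolded protein and integrated stress response list went down at 48 h, with 15 of 30 members lower and 2 higher (16 and 4 over the list alone). Besides Ddit3, Cth, which makes cysteine, fell by 2.62 (adjusted p = 0.00178) and the amino acid transporter gene Slc7a5 by 0.85 (adjusted p = 0.00266), while the endoplasmic reticulum gene Creld2 rose by 0.78 (adjusted p = 0.00199). The median was -0.43, or -0.55 relative to all genes, and was below 0 in each of 4 pairs (camera adjusted p = 2.82e-06, adjusted p = 0.509 with an estimated correlation). In IL-3 receptor and JAK-STAT5 signalling, 7 of 22 members fell and 0 rose (9 and 0 over the list alone). They included Il3ra, Socs2, a feedback inhibitor (-0.99, adjusted p = 0.00182), the kinase gene Jak2 (-0.64, adjusted p = 0.00671) and Pim3 (-0.60, adjusted p = 0.0149). The median was -0.32, or -0.44 relative to all genes (camera adjusted p = 1.41e-05, adjusted p = 0.386 with an estimated correlation).

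Of 27 genes of the BCL2 family and caspases, 8 fell and 3 rose at 48 h (8 and 3 over the list alone). The inhibitor of apoptosis gene Birc2 (-0.70, adjusted p = 0.00777), pro-apoptotic Bid (-0.62, adjusted p = 0.0108) and anti-apoptotic Bcl2l2 (-0.42, adjusted p = 0.0121) fell, and pro-apoptotic Bok rose (0.92, adjusted p = 0.00199). The list's median was -0.29 (camera adjusted p = 0.00254, adjusted p = 0.422 with an estimated correlation). Of 22 genes of the MLL-AF9 and Hoxa programme, 5 fell and 1 rose (9 and 3 over the list alone). Meis1 (-0.64, adjusted p = 0.00678) and Hoxa9 (-0.62, adjusted p = 0.0168), homeobox genes that MLL fusions activate, fell. The calls of the MLL cofactor genes Dot1l (-0.42, adjusted p = 0.035) and Men1 (0.38, adjusted p = 0.0312) were lost with the replicate block (adjusted p = 0.0538 and 0.0508), with which 8 members fell. The median was -0.38 (camera adjusted p = 0.0102, adjusted p = 0.739 with an estimated correlation).

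Granulocyte-monocyte progenitor and primary granule genes rose in 6 of 20 cases and fell in 0 (10 and 0 over the list alone), with Mpo, Plac8 (0.92, adjusted p = 0.005), Calr (1.02, adjusted p = 0.00557) and Igsf6 (1.27, adjusted p = 0.0057) among them. The median was 0.50 (camera adjusted p = 0.00432, adjusted p = 0.509 with an estimated correlation), and with the replicate block 12 members rose. Mature neutrophil markers were not called as a list (median 0.93, camera adjusted p = 0.12), although 4 of 22 rose (4 over the list alone). These were Camp, the receptor gene Csf3r (0.66, adjusted p = 0.00667), the antibacterial gene Pglyrp1 (0.97, adjusted p = 0.0103) and Anxa1 (1.41, adjusted p = 0.0422). With the replicate block 10 members rose and the list was called up (adjusted p = 0.00484), as it was without 0 h replicate 1 (0.00767) or 48 h replicate 4 (0.041). It was also called up under median scaling (4.82e-04), quantile normalization (0.0385), normexp correction (0.0273), in the deposited table (0.0261) and with the block by title number (0.0471). Of 25 monocyte and macrophage markers, 2 rose and 1 fell (median 0.59, camera adjusted p = 0.159). The Fc receptor gene Fcgr1 fell by 3.71 (adjusted p = 0.00736), and the list was called up with the block (adjusted p = 0.00912, 7 members higher) and without 0 h replicate 1 (0.0181) or 48 h replicate 4 (0.0395), as well as under median scaling (0.019) and with the block by title number (0.0131).

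The G2/M and mitosis list was called up at 48 h with a median of 0.44 (camera adjusted p = 0.0127, adjusted p = 0.858 with an estimated correlation). Only 3 of 30 members passed (0 over the list alone), namely Pttg1 (0.44, adjusted p = 0.0331), Cdk1 (0.86, adjusted p = 0.041) and Aurkb (1.22, adjusted p = 0.0419), whose groups overlapped. The list's median lay above 0 in 3 of 4 same-numbered pairs, and its call was lost without 0 h replicate 1 (adjusted p = 0.198). The MYC and ribosome biogenesis list was called down relative to other genes, with a median of -0.08, or -0.20 relative to all genes (camera adjusted p = 0.0142, adjusted p = 0.845 with an estimated correlation; 0.053 under quantile normalization). Of its 30 members, 5 fell (4 over the list alone), including Myc itself (-0.73, adjusted p = 0.0274, groups overlapping), Wdr43 (-0.45) and Rrp9 (-0.29). In G1/S and DNA replication, 4 of 29 rose (3 over the list alone), with Fen1 at 0.83, and the list was not called (camera adjusted p = 0.145). It was called up with normexp correction (0.0273), in the deposited table (0.0314) and without 0 h replicate 3 (0.0121).

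Lists close to the threshold at 48 h depended on single arrays and settings. Erythroid markers went up (4 of 14 higher, 1 lower, the same over the list alone, camera adjusted p = 0.0483, adjusted p = 0.509 with an estimated correlation), with Tfrc, the transferrin receptor, at 1.42, Epor at 0.66 and Hemgn at -0.42. The call was lost without 0 h replicate 1, 48 h replicates 1 or 2 or 96 h replicate 2 (adjusted p 0.0502 to 0.0775), and under every other scaling except the median (0.0718 to 0.185), with a median of 0.09 after normexp correction in place of 0.50. Array weights (0.0528) and a filter for probes above background on all arrays (0.143) ended it as well. Interferon-stimulated genes went down as a list (median -0.36, camera adjusted p = 0.0483, adjusted p = 0.858 with an estimated correlation) with 0 of 27 members called by limma and 2 at an unadjusted p under 0.05. That call was lost without 0 h replicates 1 or 2, 48 h replicates 3 or 4 or 96 h replicate 2 (0.0549 to 0.312), and under median scaling, quantile normalization, normexp correction and in the deposited table (0.101 to 0.132), with array weights (0.185) and with the stricter filter (0.122). Immediate early and AP-1 genes went down (1 of 26 higher, 2 lower, 1 and 1 over the list alone, camera adjusted p = 0.0495, adjusted p = 0.858 with an estimated correlation), with Jun at 1.15 (adjusted p = 0.0177) against the direction of the list. Leaving out 0 h replicates 1 or 4, 48 h replicates 3 or 4 or 96 h replicate 2 ended it (0.0575 to 0.219), as did the same 4 scalings (0.0576 to 0.151), array weights (0.0528) and the stricter filter (0.122). The histone H3 lysine 9 and 36 list (2 of 29 higher, 2 lower, the same over the list alone, median -0.15, camera adjusted p = 0.0495, adjusted p = 0.845 with an estimated correlation) held Suv39h1, a lysine 9 methyltransferase gene, at 1.06 (adjusted p = 0.0138). It was lost without 0 h replicates 2, 3 or 4, 48 h replicates 1 or 4 or 96 h replicate 2 (0.0592 to 0.145), and under every other scaling except the median (0.0896 to 0.213). The mean of a gene's probes (0.161), the block by title number (0.0616), the slide row as a term (0.0533) and the stricter filter (0.122) also ended it.

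The remaining lists were not called at 48 h. Of 28 p53 targets, 6 fell and 1 rose (7 and 2 over the list alone), with Gadd45a at -2.20 (adjusted p = 0.00219) and Sesn2 at -0.63, and the median of 0.04 and mean of -0.13 differed in sign (camera adjusted p = 0.233). In germline genes 4 of 14 rose and 1 fell, Dpep3 being at least 2.37-fold higher (adjusted p = 0.00332), with a camera adjusted p of 0.44. Megakaryocyte markers had 3 of 13 higher (adjusted p = 0.117, called up under median scaling with 0.0125), lymphoid markers 2 of 16 higher and 1 lower (0.294), stromal markers 2 of 12 higher (0.418), mast cell and basophil markers 3 of 12 higher (0.714) and dendritic cell markers 1 of 16 higher (0.485). Stem and progenitor markers had 1 of 16 higher and 2 lower, with a positive median against a downward test (0.202). NF-kB genes (1 of 21 higher, 2 lower, 0.577) and fatty acid and LXR genes (1 of 17 higher, 3 lower, 0.941) differed in sign in the same way. Lysosome genes had 1 of 29 lower, a median below and a mean above 0 (0.249), and oxidative phosphorylation 1 of 30 higher (0.757).

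The comparison of 96 h with 0 h gives the later changes. Ltf, lactoferrin, rose 113-fold (log2 difference 6.82, SE 0.58, adjusted p = 9.98e-04), Camp 52.1-fold (5.70, SE 0.61, adjusted p = 0.0024), Mpo 36.3-fold (5.18, SE 0.56, adjusted p = 0.00264) and Retnlg, a resistin-like neutrophil gene, 21.9-fold (4.45, SE 0.75, adjusted p = 0.0121). S100a8, a calprotectin subunit gene, rose 8.64-fold (3.11, SE 0.77, adjusted p = 0.0344). Fcnb, a ficolin gene not well above background on any 0 h array, was at least 3.04-fold higher (adjusted p = 0.00712). Chil1 (4.28, adjusted p = 0.00174), Ankrd22 (4.01), Ceacam10 (3.28) and Itgb2l (3.32) were further large rises, and for all of these genes the 3 arrays at 96 h lay above all 0 h arrays.

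The largest falls at 96 h included Tgfb2, at least 16.8-fold lower (adjusted p = 0.00466), the transglutaminase gene Tgm2 (-4.27, SE 0.61, adjusted p = 0.00712), Samd5, at least 2.23-fold lower (adjusted p = 0.00137), Snhg12 (-3.33, SE 0.60, adjusted p = 0.0144) and Zcchc3 (-3.31, SE 0.72, adjusted p = 0.0245). Thbs1 fell by 5.43 (SE 1.24, adjusted p = 0.0284) with an SD of 3.25 at 96 h. The groups of Col4a1 (-3.55, adjusted p = 0.0336) and Mamdc2 (-3.49, adjusted p = 0.0406) overlapped. Several calls needed particular arrays. Without any of 0 h replicates 3 and 4 and 96 h replicates 1, 2 and 3, adjusted p was 0.0665 to 0.099 for S100a8 and 0.0536 to 0.111 for Itgb2l, whose calls were also lost with the slide row as a term (0.0511 and 0.0518). Leaving out 96 h replicates 1 or 3 ended the call of Ankrd22 (0.05 and 0.0524), and leaving out 0 h replicate 4 or 96 h replicates 2 or 3 that of Zcchc3 (0.0589 to 0.0789). The calls of Thbs1, Col4a1 and Mamdc2 were lost without any of 0 h replicates 1, 3 and 4 and 96 h replicates 2 and 3 (0.0581 to 0.122), that of Col4a1 also without 96 h replicate 1 (0.0551) and that of Mamdc2 also without 48 h replicates 1, 2 or 4 (0.055 to 0.056). Fcnb was not called after normexp correction (0.44, adjusted p = 0.0906) or in the deposited table (0.0892). Zcchc3 was well above background on 1 of 3 arrays at 96 h. With only the 2 groups compared, 8 of the genes with the largest changes, Ceacam10 and Snhg12 among them, lost their calls (0.0516 to 0.0901). Without a filter on dim probes, S100a8, Itgb2l, Thbs1, Col4a1 and Mamdc2 did (0.0549 to 0.0725), and Mamdc2 also with the block by title number (0.0691) and with trend and robust eBayes (0.0543).

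**Figure D2:**
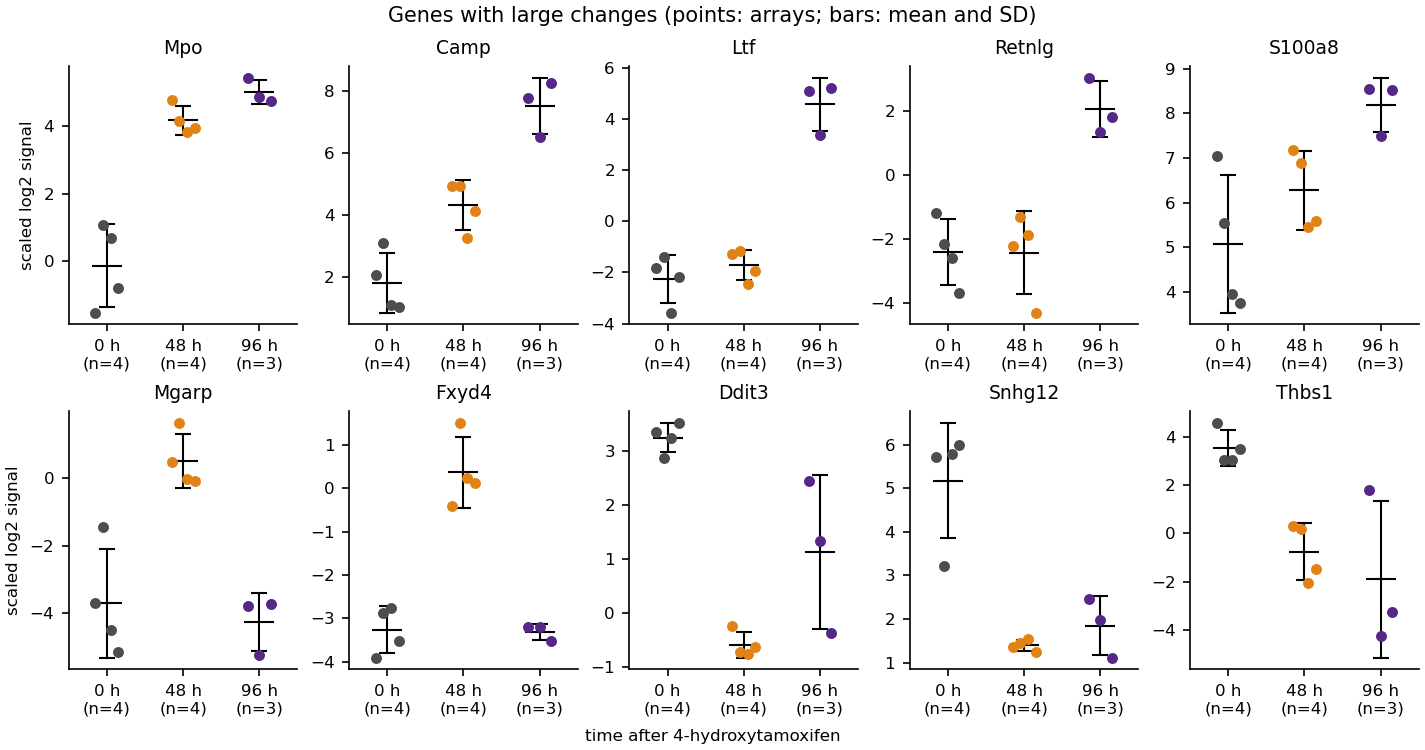
Scaled log2 signal of each array at 0 h, 48 h and 96 h for 10 genes with large changes, with points for arrays and bars for the mean and SD. Ltf and Camp were higher at 96 h than at 0 h by 6.82 and 5.70 on the log2 scale, and Thbs1 spread widely at 96 h (SD 3.25).

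At 96 h against 0 h, 2397 genes passed, 1549 higher and 848 lower, 640 of them by at least 2-fold. The count was 435 with only the 2 groups compared, 910 without a filter on dim probes and 1484 with the block by title number. The replicate block by file-name number raised the number lower to 1366. The median difference of all genes was 0.11 with the main scaling and -0.28 with median scaling. The split was 979 higher and 1162 lower with quantile normalization, 231 and 2328 with median scaling, 1235 and 1358 with normexp correction, and 1359 and 1282 in the deposited series table. The 96 h replicate 1 array stood apart, with 75.8% of spots well above background against 50.2% to 64.7% on the other arrays, and without it 932 genes passed. Other left-out arrays gave 1311, 1022 and 973 (0 h replicates 1, 3 and 4) and 702 and 896 (96 h replicates 2 and 3).

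Of 22 mature neutrophil markers, 7 rose and 0 fell at 96 h (11 and 0 over the list alone), with Ltf, Camp, Retnlg and Pglyrp1 (1.39, adjusted p = 0.00847) among them. The median was 2.05, or 1.94 above all genes, and lay between 1.51 and 3.18 in the 3 same-numbered pairs (camera adjusted p = 5.98e-06, adjusted p = 0.739 with an estimated correlation). With the replicate block 16 members rose, and without 96 h replicate 1 the median was 1.93 with 4 members called. In the granulocyte-monocyte progenitor list, 6 of 20 rose and 0 fell (8 and 0 over the list alone), including Mpo, Fcnb, Clec12a (1.39, adjusted p = 0.0105) and Igsf6 (1.22, adjusted p = 0.0157). Its median was 0.65 (camera adjusted p = 0.00298, adjusted p = 0.509 with an estimated correlation), with 13 members called with the block and 4 without 96 h replicate 1. Stem and progenitor markers went down as a list (2 of 16 lower, the same over the list alone, camera adjusted p = 0.0495, adjusted p = 0.739 with an estimated correlation), with Gata2 at -0.80 (adjusted p = 0.031) and Etv6 at -0.52. The replicate block ended the calls of Etv6 (adjusted p = 0.0671) and of the list (0.0854). The list's call was also lost on leaving out any single array except 0 h replicate 2, 48 h replicate 1 or 96 h replicate 2 (0.0518 to 0.108), under all 5 other scalings (0.0515 to 0.163), with the block by title number (0.058) and with the stricter filter (0.122).

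Stress response genes remained lower at 96 h, with 8 of 30 members of the unfolded protein and integrated stress response list lower and 1 higher (8 and 3 over the list alone). Ppp1r15a, a phosphatase subunit gene of that response, fell by 1.82 (adjusted p = 0.0121), and the transporter subunit genes Slc3a2 and Slc7a5 by 0.79 (adjusted p = 0.0219) and 0.59 (adjusted p = 0.0225), while Hsp90b1 rose by 0.53. The list median was -0.32 (camera adjusted p = 1.58e-04, adjusted p = 0.739 with an estimated correlation). Of 26 immediate early and AP-1 genes, 5 fell and 0 rose (5 and 0 over the list alone), with Jun at -1.31 (adjusted p = 0.0258), Jund at -0.71 (adjusted p = 0.0302), Ier2 at -0.56 (adjusted p = 0.0372) and the phosphatase gene Dusp4 at least 1.59-fold lower. Without 96 h replicate 1, 3 were lower. The median was -0.50 (camera adjusted p = 1.58e-04, adjusted p = 0.739 with an estimated correlation). Of 27 BCL2 family and caspase genes, 3 fell and 0 rose (3 and 0 over the list alone), namely Bok (-0.81, adjusted p = 0.00811), Bid (-0.66, adjusted p = 0.0204) and anti-apoptotic Bcl2l1 (-0.66, adjusted p = 0.0212). Their list median was -0.18 (camera adjusted p = 9.48e-04, adjusted p = 0.386 with an estimated correlation).

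The cholesterol list was still higher at 96 h (median 0.54, camera adjusted p = 0.00137, adjusted p = 0.858 with an estimated correlation), with 3 of 26 members called (4 over the list alone). Hmgcs1 was among them (0.68, adjusted p = 0.0139), and 6 members rose with the replicate block but 1 without 96 h replicate 1. In IL-3 receptor and JAK-STAT5 signalling, 6 of 22 members fell and 1 rose (7 and 1 over the list alone). Besides Il3ra, the STAT5 feedback gene Cish fell by 0.97 (adjusted p = 0.00372) and Pim3 by 0.77 (adjusted p = 0.0155), and Spred2 rose by 0.62 (adjusted p = 0.0205). That list's call (camera adjusted p = 0.0113, adjusted p = 0.509 with an estimated correlation) was lost with the replicate block (adjusted p = 0.0561) and under quantile normalization (0.105). Of 32 hypoxia and glycolysis genes, 2 fell, Ero1a (-0.95, adjusted p = 0.0157) and Vegfa (-0.55, adjusted p = 0.0227), the same over the list alone. The list's downward call (median -0.05, camera adjusted p = 0.0495, adjusted p = 0.845 with an estimated correlation) turned to a median above 0 with normexp correction (0.025), quantile normalization (0.019) and the deposited table (0.043), without a call under these (adjusted p 0.798 to 0.911) or under the added percentile (0.0705). Array weights (0.124), the mean of a gene's probes (0.117), the slide row as a term (0.0582) and the stricter filter (0.143) ended it too. It was lost with the replicate block (adjusted p = 0.146) and without 0 h replicates 1 or 2, 48 h replicates 2, 3 or 4 or 96 h replicates 2 or 3 (0.0517 to 0.207).

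Cell cycle lists went up at 96 h. The G2/M and mitosis list had a median of 0.60 (camera adjusted p = 0.00401, adjusted p = 0.858 with an estimated correlation) with 0 of 30 members called by limma and 7 higher at an unadjusted p under 0.05. In G1/S and DNA replication, 2 of 29 rose and 1 fell (9 and 1 over the list alone), the ligase gene Lig1 at 0.79, Orc1 at 0.65 and E2f2 at -0.69. Its median was 0.29, or -0.10 and not called (0.0965) under median scaling (camera adjusted p = 0.00699, adjusted p = 0.858 with an estimated correlation). Fitted with the block, 6 members rose. Leaving out 0 h replicate 1 ended the calls of G2/M (adjusted p = 0.108) and G1/S (0.107). The MYC list went down relative to other genes (median -0.10, camera adjusted p = 0.00492, adjusted p = 0.845 with an estimated correlation), with Rrp9 (-0.40, adjusted p = 0.0169), Imp4 (-0.45) and Wdr43 (-0.47) lower and 0 of 30 higher (3 and 0 over the list alone). With the block 6 members fell and without 96 h replicate 1 only 1, and the list was not called under quantile normalization (0.0844). Of 28 p53 targets, 3 fell and 1 rose (4 and 3 over the list alone), with Gadd45a at -1.54 (adjusted p = 0.018), Pmaip1 at -0.73, Sesn2 at -0.53 and Ercc5 at 0.45. That list's call (camera adjusted p = 0.042, adjusted p = 0.739 with an estimated correlation) was lost without 0 h replicates 1 or 4 or 96 h replicate 2 (0.0627 to 0.126), and under quantile normalization (0.145), normexp correction (0.132), in the deposited table (0.113) and with the stricter filter (0.122). Fitted with the block, 7 of its members fell.

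Other lists were not called at 96 h against 0 h. The MLL-AF9 and Hoxa list had 0 of 22 members called by limma and 2 higher and 5 lower at an unadjusted p under 0.05, with a median of 0.09 and a mean of -0.02 (camera adjusted p = 0.248). Monocyte markers had 2 of 25 higher (0.462), Apoe at 0.64 and the NADPH oxidase gene Cybb at 2.66, and interferon-stimulated genes 0 of 27 called by limma and 1 higher unadjusted (0.838). With the replicate block these lists were called up (adjusted p = 0.0278, with 8 monocyte markers higher, and 0.0363), the interferon list also without 96 h replicate 3 (0.0259). The interferon median was 0.24, and -0.35 without 96 h replicate 1. NF-kB genes (2 of 21 lower, 0.0626) were called down without 0 h replicates 3 or 4 or 96 h replicate 1 (0.00362 to 0.0446), with the mean of a gene's probes (0.0447), with only the 2 groups compared (0.0321) and with the block by title number (0.02). Lymphoid markers had 2 of 16 higher and 2 lower (0.577), with the T cell receptor gene Cd3d at 1.55 (adjusted p = 9.98e-04). Megakaryocyte markers had 2 of 13 higher (0.133, and called up under median scaling with 0.00958 and with the mean of a gene's probes with 0.0474), Tubb1 at least 1.48-fold and Gp9 by 1.43, the histone H3 lysine 9 and 36 list 3 of 29 higher (1 without 96 h replicate 1) and 1 lower (0.783), and the lysosome list 1 of 29 higher (0.558). Fatty acid and LXR genes had 1 of 17 higher and 1 lower (0.462). Signs of median, mean or test differed for dendritic (1 of 16 higher, 1 lower, 0.44), mast cell (1 of 12 lower, 0.577), germline (1 of 14 higher, 1 lower, 0.983) and erythroid markers (2 of 14 higher, 1 lower, 0.983). They also differed for stromal markers (0 of 12 called by limma and 0 unadjusted, 0.941) and oxidative phosphorylation (0 of 30 called, 3 higher and 4 lower unadjusted, 0.462).

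**Figure D3:**
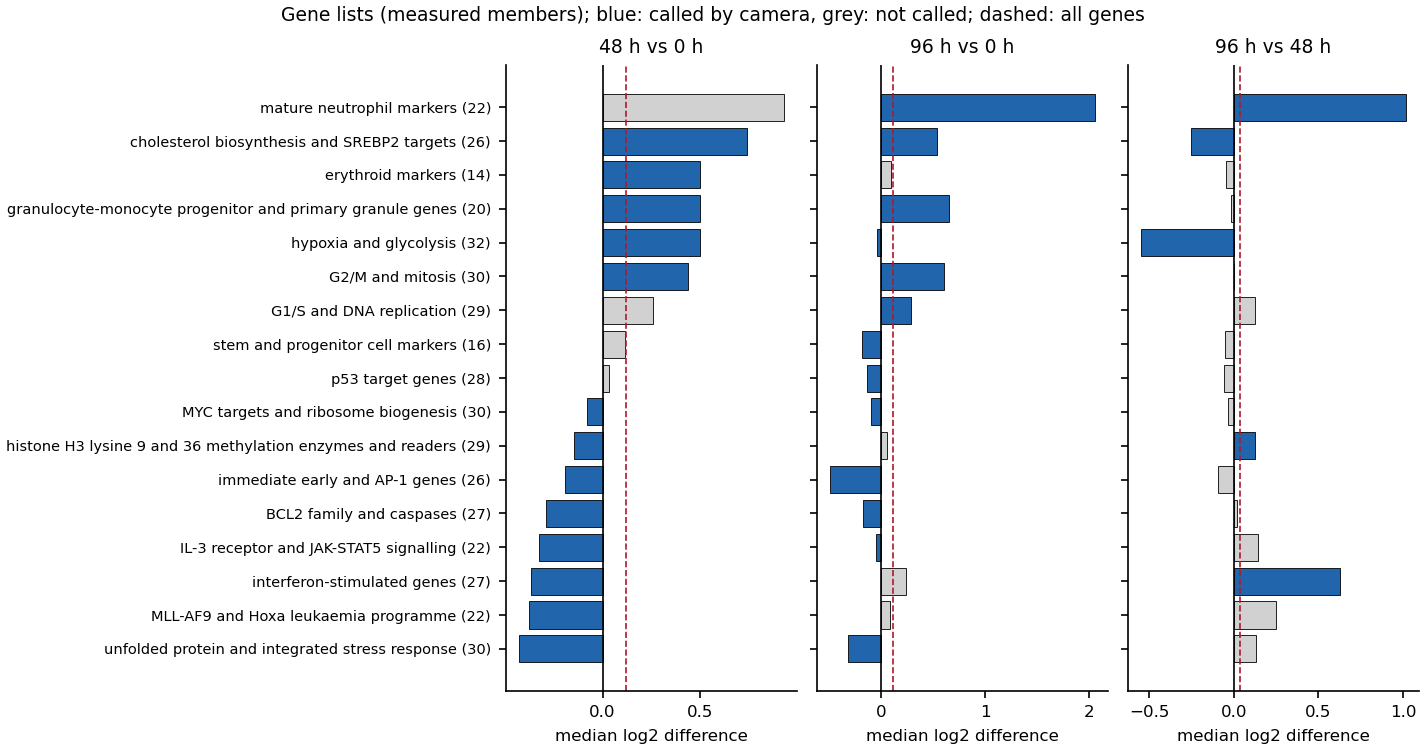
Median log2 difference of the members of 17 gene lists called at least once, for each of the 3 comparisons, with coloured bars where camera called the list, grey bars where it did not, and a dashed line at the median of all genes. The neutrophil list reached 2.05 at 96 h against 0 h, and the hypoxia and glycolysis list stood at 0.50 at 48 h against 0 h and -0.55 at 96 h against 48 h; at 96 h against 0 h its sign turned under normexp correction, quantile normalization and the deposited table, as did, under median scaling, that of G1/S genes at 96 h against 0 h and of the histone H3 lysine 9 and 36 list at 96 h against 48 h.

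Comparing 96 h directly with 48 h shows what changed between the time points, with the slide changing as well. Ltf rose 78.1-fold (log2 difference 6.29, SE 0.58, adjusted p = 0.00219) and Retnlg by 4.47 (SE 0.75, adjusted p = 0.00791), while Mgarp fell by 4.74 (SE 0.80, adjusted p = 0.00806), Fxyd4 by 3.67 (SE 0.42, adjusted p = 0.00295) and Smtnl2 by 2.93 (SE 0.57, adjusted p = 0.0129). All 3 arrays at 96 h lay on the same side of all 48 h arrays for these genes. Other large changes were those of Syt10 (4.06, adjusted p = 0.0274), Ankrd22 (3.48, adjusted p = 0.0186), Dnm1 (3.37, adjusted p = 0.0279) and the globin gene Hbb-bt (-2.83, adjusted p = 0.0429). The calls of Syt10 and Dnm1 were lost without any of 48 h replicates 1 and 2 and 96 h replicates 1, 2 and 3 (adjusted p 0.0586 to 0.0834), that of Ankrd22 without 48 h replicate 4 or 96 h replicates 1 or 3 (0.0515 to 0.0728). Hbb-bt lost its call without 0 h replicates 3 or 4, 48 h replicates 2, 3 or 4 or any 96 h array (0.0544 to 0.14), under median scaling (0.0518), with the slide row as a term (0.0645) and with trend and robust eBayes (0.0548). Without a filter on dim probes, Hbb-bt (0.0801), Syt10 (0.054) and Dnm1 (0.0553) lost their calls.

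Between 48 h and 96 h, 2789 genes passed, 1296 higher and 1493 lower, 597 of them by at least 2-fold. The count was 1367 without a filter on dim probes and 1600 with the block by title number. Under median scaling the split was 158 higher and 762 lower, with a median of all genes of -0.13 in place of 0.03. Without 96 h replicate 1, 988 genes passed, and without 96 h replicate 3, 1429. Without 48 h replicates 1 or 4 the counts were 1586 and 1412.

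The hypoxia and glycolysis list fell from 48 h to 96 h, with 17 of 32 members lower and 0 higher (18 and 1 over the list alone). Bnip3 (-1.34, adjusted p = 0.00254), Ankrd37 (-2.23, adjusted p = 0.00262), Pgk1 (-1.12, adjusted p = 0.00295) and the lactate transporter gene Slc16a3 (adjusted p = 0.00295) fell. The median was -0.55, with -0.56 to -0.48 in the 3 same-numbered pairs (camera adjusted p = 4.35e-08, adjusted p = 0.386 with an estimated correlation). Of 22 mature neutrophil markers, 4 rose and 0 fell (5 and 1 over the list alone), namely Ltf, Retnlg, Camp (3.21, adjusted p = 0.0119) and Itgb2l (3.20, adjusted p = 0.0353). Their list rose (median 1.01, camera adjusted p = 0.00254, adjusted p = 0.845 with an estimated correlation), with 10 members called with the replicate block.

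Interferon-stimulated genes went up between the time points (median 0.63, camera adjusted p = 0.0443, adjusted p = 0.858 with an estimated correlation), with Stat2 (0.77, adjusted p = 0.0192) and Ifit2 (0.62, adjusted p = 0.0289) the 2 of 27 members that rose (2 over the list alone). With the replicate block 12 rose. The call was lost without 96 h replicate 1 (median 0.16, adjusted p = 0.499), 96 h replicate 2 (0.103), 48 h replicate 3 (0.0859) or 48 h replicate 4 (0.21), with only the 2 groups compared (0.071) and with the slide row as a term (0.0734). In the histone H3 lysine 9 and 36 list, 4 of 29 rose and 0 fell (5 and 1 over the list alone), the demethylase-family genes Phf2 (2.14-fold, adjusted p = 0.00466) and Jmjd1c (0.82, adjusted p = 0.0116), the methyltransferase gene Nsd2 (0.61) and Atrx (0.55). Without 96 h replicate 1, 2 rose. The list's upward call (median 0.12, camera adjusted p = 0.0483, adjusted p = 0.845 with an estimated correlation) turned to a median of -0.04 under median scaling (0.189). It was lost under quantile normalization (0.0514) and the added percentile (0.0515), with only the 2 groups compared (0.15), with the mean of a gene's probes (0.123), with the block by title number (0.0616) and without 0 h replicates 1 or 4, 48 h replicates 1 or 4 or 96 h replicate 2 (0.0517 to 0.169). Cholesterol genes went down (median -0.25, camera adjusted p = 0.0495, adjusted p = 0.858 with an estimated correlation), with 3 of 26 lower (3 over the list alone). These were Sqle (-0.41), Acat2 (-1.02) and Hsd17b7 (-0.70), and with the replicate block the list was not called (adjusted p = 0.236), nor were Acat2 (0.0776) and Hsd17b7 (0.0732). Leaving out 0 h replicates 1 or 3, 48 h replicates 2, 3 or 4 or 96 h replicates 1 or 2 also ended it (0.0537 to 0.259), as did median scaling, quantile normalization and the added percentile (0.0583 to 0.0863), the slide row as a term (0.0778) and the stricter filter (0.122). No member passed limma's test without 96 h replicate 1.

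The lists not called between 48 h and 96 h held single genes with clear changes. Bok fell by 1.73 (adjusted p = 0.00115) in a BCL2 list with 2 of 27 higher and 2 lower (camera adjusted p = 0.941). Jun fell by 2.46 (adjusted p = 0.00304), with 2 of 26 immediate early genes lower (0.159), a list called down without 96 h replicate 1 (0.00973). Cth rose by 2.11, with 3 of 30 stress response genes higher (1 without 96 h replicate 1) and 1 lower (0.133), a list called up without 96 h replicate 3 (0.0166), with normexp correction (0.00678), under quantile normalization (0.00837) and in the deposited table (0.0035). In the MLL-AF9 list 4 of 22 rose and 2 fell (0.201), with Dot1l at 0.87, Men1 at -0.63 and the receptor gene Flt3 at -0.93. In IL-3 signalling 4 of 22 rose and 2 fell (0.249), with Spred2 at 0.81, Jak2 at 0.55 and Cish at -0.63. Without 96 h replicate 1, 2 members of the MLL-AF9 list and 1 of the IL-3 list rose. Tspan33 was at least 2.55-fold lower, with 2 of 14 erythroid markers lower (0.106, and called down without a filter on dim probes with 0.0482).

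Among the other lists, lysosome genes (1 of 29 higher, 0.106) were called up with the replicate block (adjusted p = 0.0229) and without 48 h replicate 2 (0.0312), with normexp correction (0.0319), in the deposited table (0.0255) and without a filter on dim probes (0.0482). Dendritic cell markers (2 of 16 lower, 0.13) were called down without 48 h replicate 4 (0.0451) or 96 h replicate 1 (0.0464), with the mean of a gene's probes (0.0474) and with the block by title number (0.011), and NF-kB genes (1 of 21 lower, 0.32) without 96 h replicate 1 (0.0326) and with that block (0.0314). Camera adjusted p was 0.331 for G1/S genes (Ccne1 at -0.56, 1 of 29 lower), 0.92 for G2/M genes (1 of 30 higher), 0.212 for oxidative phosphorylation (1 of 30 higher), 0.558 for p53 targets (1 of 28 higher, 2 lower), 0.215 for mast cell markers (1 of 12 lower) and 0.323 for stromal markers (1 of 12 lower). It was 0.657 for stem and progenitor markers, with 0 of 16 called by limma and 3 higher and 2 lower unadjusted. Signs of median, mean or test differed for MYC (1 of 30 higher, 1 lower, 0.757), germline (2 of 14 lower, 0.351), fatty acid (3 of 17 higher, 1 without 96 h replicate 1, 0.462) and monocyte genes (1 of 25 lower, 0.577). They also differed for lymphoid (1 of 16 higher, 2 lower, 0.947), granulocyte-monocyte progenitor (2 of 20 higher, 1 lower, 0.956) and megakaryocyte markers (0 of 13 called by limma, 2 lower unadjusted, 0.983).

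The comparisons of 48 h and 96 h with 0 h share the same 4 control arrays. They had 1155 called genes in common, of which 1097 changed in the same direction (576 higher and 521 lower) and 58 in opposite directions, 44 of them higher at 48 h and lower at 96 h. Independent lists of these sizes would share 231 in the same direction, and in 100 simulations of unchanged groups against shared controls the largest count was 0. With no gene changed hardly any gene is called, so that count does not show how far shared controls raised the overlap. The log2 differences of the comparisons correlated at 0.543 across genes, which are not independent replicates, against 0.462 in the simulations, and their covariance was 0.145 against 0.0375, a difference of 0.107. With the controls split between the comparisons, 76 to 374 genes were called in the same direction and the covariance was 0.0918 to 0.114. The count in the same direction was 378 without a filter on dim probes, 731 with the block by title number and 1669 with array weights. Leaving out 0 h replicates 1, 2, 3 and 4 in turn gave 538, 1868, 437 and 466 genes in common in direction, leaving out 48 h replicates 1 and 4 gave 699 and 658, and leaving out 96 h replicates 1, 2 and 3 gave 572, 346 and 483.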

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

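The tests of the hypoxia list's shift under other scalings, of MYC-driven growth, of cycling cells and of the separate slide were chosen only after the result was seen. In each comparison the real grouping was the only 1 of 35 splits of the arrays to call as many genes (4657, 2397 and 2789). This is the smallest share that 35 splits allow. It lies under 0.05 but comes from splits that ignore the pairing, so it does not by itself exclude chance. Each other split mixes arrays of both real groups, so any real difference widens its within-group spread and lowers its count. The other counts therefore do not show what arrays without a difference would give. The highest other count was 1 at 48 h against 0 h, 1 at 96 h against 48 h and 1426 at 96 h against 0 h. Among the splits that part all same-numbered pairs, as the real one does, the highest other counts were 0, 1 and 1426, but with 8 such splits a share under 0.05 cannot be reached. The split with 1426 genes set 0 h replicate 2 with the 3 arrays at 96 h, and moving any other single 0 h array gave 0 genes. By file-name number, 0 h replicate 2 is the only 0 h array without a partner at 96 h, so moving it parts all pairs and moving another joins a pair. At 96 h against 48 h, 48 h replicate 2 likewise has no partner at 96 h, and moving it gave 0 genes. Parting all pairs therefore does not by itself account for the 1426 genes. Without 0 h replicate 2, the count at 96 h against 0 h rose from 2397 to 3293.

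Single arrays far from the rest of their group were found in 10 of 140 groups of 4 tested, and chance flags about 1 in 20 groups. At 0 h, Snhg12 in replicate 2 was at 3.21 against 5.71 to 6.00 on the others, and Samd5 in replicate 1 at -3.05 against -3.86 to -3.73. In 0 h replicate 1, the median level of the MLL-AF9 and Hoxa list was 1.53 against 1.23 to 1.28, and that of the G1/S list 3.79 against 4.20 to 4.24. At 48 h, Mamdc2 in replicate 3 was at -2.18 against -3.99 to -3.91, and Ankrd22 in replicate 1 at -2.30 against -4.67 to -4.32. Median list levels far from the others at 48 h were 2.93 for stem and progenitor markers (replicate 2, others 2.57 to 2.63), 3.63 for G2/M (replicate 3, others 3.12 to 3.20), 4.21 for hypoxia and glycolysis (replicate 2, others 3.67 to 3.76) and 2.91 for cholesterol genes (replicate 1, others 3.01 to 3.02).

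Among the genes and lists picked by rule, Bok, Jun and the hypoxia and glycolysis list were called in opposite directions at 48 h and 96 h against 0 h and also differed in the test of 96 h against 48 h. Bok was 0.92 above its 0 h level at 48 h and -0.81 relative to it at 96 h, a difference of -1.73. Jun went from 1.15 to -1.31, a difference of -2.46. The hypoxia and glycolysis list moved by -0.55 between the time points, but its call at 96 h against 0 h (median -0.05, adjusted p = 0.0495) was lost with the replicate block (adjusted p = 0.146), and its median there turned positive under normexp correction, quantile normalization and in the deposited table (0.025, 0.019 and 0.043).

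For the hypoxia and glycolysis list at 48 h, the largest camera adjusted p under 5 other scalings was 0.0014. This argues against scaling between arrays as the cause of the list's shift against all other genes. A changed reference per array, as with median scaling, moves all genes alike and could hardly alter that comparison. The number of members called was a test chosen before the result was seen. It did depend on the scaling, with as few as 7 called higher under median scaling in place of 18. If same-numbered arrays share a culture, a single deviating culture is excluded, as the lowest median difference over the 4 same-numbered pairs was 0.40. MYC-driven growth predicted a higher MYC list, whereas that list changed by -0.19 on average relative to all genes, with -0.32 to -0.11 over the pairs. This argues against MYC-driven growth, although a rise of all transcripts alike could not be seen in scaled values. Loss of the demethylases, exposure to the drug or the recombinase, and time in culture went together and stay open, untested.

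For the mature neutrophil list at 96 h, the 96 h replicate 1 array had the most spots above background, and without it the list median was 1.93 with 4 members called higher in place of 7. A part played by that array in the number of calls stays open. Fewer cycling cells predicted a lower G2/M list, whereas that list was above all genes by at least 0.16 in each of 3 same-numbered pairs. These values give no sign of fewer cycling cells in the cultures as a whole. They share the change of slide, 0 of 30 members were called, and the list's call was lost without 0 h replicate 1. Fewer cycling cells are therefore not excluded. A subset of cells that stopped cycling could not be seen in values of whole cultures and stays open. The separate slide cannot be told apart from 96 h, because all 96 h arrays lay on a slide of their own. Within the slide of the 0 h and 48 h arrays, the neutrophil median at 48 h lay 0.054 to 1.07 above all genes over the 4 pairs. Those values concern 48 h and cannot separate slide from time at 96 h. Loss of the demethylases, the drug or the recombinase, and time in culture are also open and untested.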

How the results depend on the processing

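The percentile over probes well above background on all arrays was the only one of these tests chosen after the data were seen. Of 379 named gene results 257 were called, 91 of them under every alternative, and of 9418 alternative values 7856 kept direction and side of the threshold, 1196 lost and 363 gained a call, and 3 reversed. The reversed ones were Nr1h2 at 96 h against 0 h under median scaling (-0.0025), and at 96 h against 48 h Srgn in the deposited table (0.042) and Itgam with the mean of a gene's probes (0.0062). None of the 28 lists fixed beforehand reversed a call. The cause was not tested except where fewer arrays, more tests or a stricter threshold make it plain.

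Median scaling gave 2355 genes at 48 h against 0 h and 920 at 96 h against 48 h. Without a filter on dim probes, with more genes tested, the counts were 2652, 910 and 1367 for 48 h against 0 h, 96 h against 0 h and 96 h against 48 h, with an overlap of 378. The dim Kdm4a probe then kept its differences of -1.46 at 96 h against 0 h and -1.23 at 96 h against 48 h and lost both calls, and its later fall was not called after normexp correction (-0.12) or in the deposited table (-0.12). With only the 2 groups compared, 96 h against 0 h gave 435 genes. Array weights gave an overlap of 1669. An adjusted p under 0.01 left 1185, 193 and 555 genes, and a change of at least 2-fold 904, 640 and 597. With split controls the overlap was 235, 76, 168, 374, 170 and 88.

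With the replicate block by file-name number the counts were 5368, 3514 and 3051, with an overlap of 1590. Of the 379 named gene results 16 lost and 39 gained a call with it. Srgn at 96 h against 48 h was among those that lost it (adjusted p = 0.0558). Beyond Srgn and the calls given beside the results, the block changed no call for a gene in the comparison for which the report names it, nor for a list. Smaller counts that it moved were those of germline (4 higher) and lymphoid markers (4 higher) and hypoxia genes (4 lower) at 96 h against 0 h. At 48 h against 0 h, 4 lymphoid markers were higher and 4 genes of the histone H3 lysine 9 and 36 list lower, and at 96 h against 48 h 4 dendritic cell markers and 4 p53 targets were lower. With the block by title number they were 1484 at 96 h against 0 h and 1600 at 96 h against 48 h, with an overlap of 731. Slide as a block was not run, because slide 2 held only the 96 h arrays.

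Leaving out each array in turn gave 2447 to 5431 genes at 48 h against 0 h, 702 to 3293 at 96 h against 0 h, 988 to 2970 at 96 h against 48 h and an overlap of 346 to 1868. The dim Kdm4a probe ranged from -1.74 to -1.11 at 96 h against 0 h and from -1.51 to -0.88 at 96 h against 48 h. Without 96 h replicate 1, all 2397 and 2789 genes called at 96 h against 0 h and against 48 h kept their sign, and 865 and 923 kept their call. Signal over background limits what can be seen of dim genes: 50.2% to 75.8% of spots were well above background per array, and for genes below it in 1 group only a bound on the fold is given.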

Other observations

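The tests of small nucleolar RNA host genes and of Rhox genes were chosen only after their values were seen, whereas the lists of decay factors and of ribosomal protein genes were drawn up, after the host genes' fall was seen, as tests of it before their own values were seen. Host genes of small nucleolar RNAs, whose introns release the RNAs that guide ribosomal RNA modification, fell at 48 h. Of 11 measured, 6 fell and 1 rose: Snhg12 (-3.78, adjusted p = 0.00335), Snhg1 (-2.49, adjusted p = 0.00484), Snhg16 (-2.39, adjusted p = 0.0125), Snhg5 (-2.26, adjusted p = 0.00729), Snhg7 (-0.81) and Snhg6 (-0.68) fell, and Snhg3 (1.05, adjusted p = 0.00205) rose. The median was -0.68 (camera adjusted p = 0.00237, adjusted p = 0.276 with an estimated correlation), and -0.90 to -0.62 under other scalings. At 96 h 5 were lower and 0 higher (median -0.67, camera adjusted p = 5.0e-05, adjusted p = 0.261 with an estimated correlation). Camera p-values of the host gene, decay factor and ribosomal protein lists were adjusted over these lists alone, apart from the lists fixed beforehand. The host gene list was chosen from the same values that it was tested on, so its p-values are not an independent test.

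Nonsense-mediated decay factors, which degrade transcripts with premature stop codons, went down at 48 h, with 5 of 10 lower and 0 higher, among them Upf3b (-0.70), Smg1 (-0.61), Upf2 (-0.56) and Smg9 (-0.54). Their median was -0.38 (camera adjusted p = 2.56e-04, adjusted p = 0.261 with an estimated correlation), and 5 were lower under each of the other scalings. The homeobox gene Rhox10, like Rhox5 on the X chromosome, rose by 1.38 at 48 h (adjusted p = 0.0257) and fell by 2.19 from 48 h to 96 h (adjusted p = 0.00942), to -0.81 relative to 0 h (adjusted p = 0.2). The other measured Rhox genes were not called at 48 h: Rhox9 (0.17, adjusted p = 0.635), Rhox4e (0.50, adjusted p = 0.236) and Rhox1 (0.28, adjusted p = 0.358).

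Of 37 ribosomal protein and elongation factor genes, 16 were lower at 96 h than at 48 h (median -0.43, camera adjusted p = 1.84e-12, adjusted p = 0.276 with an estimated correlation), but the median was 0.11 with normexp correction, 0.10 with quantile normalization and 0.16 in the deposited table, where 12 were higher. Under median scaling the median was -0.59. The number lower was 2 without 96 h replicates 1 or 3, 3, 7 and 9 without 48 h replicates 4, 3 and 1, 10 without 0 h replicate 4, and 25 with the replicate block.

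For the lower small nucleolar RNA host genes at 48 h, more nonsense-mediated decay predicted lower transcripts of the decay factors, which the pathway represses, and their median was -0.50 relative to all genes (mean over 4 same-numbered pairs). The hypothesis stays open, with decay itself not measured. Fewer transcripts of the decay factors would also go with less decay, so these values cannot decide it. Lower output of ribosomal protein and translation factor genes predicted lower transcripts of them at 48 h. Their median instead lay 0.0050 to 0.088 above that of all genes over the 4 pairs (mean 0.038). This argues against lower output at 48 h under the main scaling, as far as transcript levels show it. The list's position depended on the scaling in other comparisons, so lower output is not excluded. At 96 h against 0 h the host genes were lower as well. The ribosomal protein list's median difference was then -0.26 (camera adjusted p = 6.44e-11, adjusted p = 0.276 with an estimated correlation). It was -0.0014 in the deposited table, so these values do not argue against lower output at that time. Other causes, the loss of the demethylases among them, were not tested.

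The 96 h replicate 1 array had 55.1% of olfactory receptor probes well above background against 13.9% to 30.7% on the others, with a median scaled log2 signal of -4.63 against -6.89 to -5.73. Of 16194 probes named only by a chromosome interval, 69.5% were well above background on it against 34.2% to 54.0%.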
